A study of Homo sapiens with 12 samples.

How the data were processed

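The samples were 3 iCLIP libraries of IGF2BP3 from each of RS4;11 and REH, and 3 RNA-seq libraries each of RS4;11 cells with control or IGF2BP3 shRNA. Cytosolic extracts were used for both assays and polyadenylated RNA was selected for RNA-seq, per the labels' protocols. Samples were grouped by the titles in the labels, with their replicate numbers.

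The submitters' processing notes name Bowtie2, TopHat, STAR, bedtools and DESeq and the build hg19, with no versions, roles or order. The deposited knockdown table holds, per the file headers, normalized mean signal (read counts scaled and averaged by DESeq) for all, control and knockdown libraries. The authors' fold column is a ratio of knockdown to control means, which was checked to within 6.27e-05 percent. The authors' log2 column is the log2 of that ratio and is infinite for 15 entries with a mean listed at 0. The authors' p-value columns are raw and adjusted. Adjusted and raw p-values together implied 13278 tests, and the table held the 2476 entries under 0.1. The iCLIP peaks were called with CLIPper per library on hg19, per the file headers, with a p-value deposited for each peak. The peak names end in a number that was read as reads per peak, as CLIPper writes it, with a minimum of 6; no source used here states this, and the report uses it only to describe peaks and to break ties when peaks are ranked by p-value, while read shares in the closing section rest on it. Peak p-values only ranked peaks within a library. Because the values were no raw counts, no count model was run.

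Symbols were matched to current names with a table of gene IDs and with RefSeq names of the GRCh38.p14 assembly, used for names only. Of the table's entries, 2464 matched and 12 did not, 8 symbols stood on more than 1 entry, and the entry with the smaller p was kept, leaving 2466 genes; infinite fold changes were left out of medians and list tests. Between 90.3% and 94.2% of peaks per library had an ID with a symbol. Depth per library was unknown. Confidence intervals cover counting error only.

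Before the data were examined, 24 gene lists, the tests and the rule for named genes were fixed. Named were IGF2BP3, the 12 largest falls and 12 largest rises at an adjusted p below 0.05 and a mean of 10 or more, up to 4 members per list past the threshold by adjusted p, the 10 genes per line with the most peaks, up to 8 genes per line bound in that line alone, genes linked to IGF2BP proteins earlier, and up to 10 bound genes per direction. From these the text gives a part, and some genes that the rule names are not reported here. Lists with 5 or more members in the table were tested with cameraPR of limma 3.58.1 in R 4.3.3 on signed z values from the authors' p-values, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 14 lists. Other tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and, for plots, matplotlib 3.10.9. The list and bound-gene tests compare genes within a table already selected on p. Libraries were compared by exact permutation, where 3 against 3 gives no p under 0.1. A gene was called bound with a peak in 2 or more of 3 libraries. The permutation p of bound against unbound genes used the distance from the median of the permuted differences, and the distance from 0 gave 0.0132.

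The tests were tried on simulated data. In 100 shuffles of fold changes over 2451 genes, 3% gave a permutation p under 0.05 for bound against unbound genes, and moving bound genes by -1 gave p = 0.000999, the smallest that its resamples allow. Of 200 random lists 2.50% gave p under 0.05 in the list test, and 30 genes moved upward gave 4.2e-12. Shuffling values over genes removes any correlation between them. These trials therefore do not show how the tests behave for families of genes that vary together.

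Alternatives were other thresholds, filters on mean level, other correlations and statistics for lists, stricter peaks, other overlaps, pairing by replicate number and leaving out each iCLIP library. Planned results on the location of peaks in transcripts and on sequence motifs need an hg19 annotation and genome, which were not used here. No value per RNA-seq library was used, so libraries of the knockdown could not be left out, paired or regrouped.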

Results

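The series measured where the RNA-binding protein IGF2BP3 contacts RNA in leukemia cells and how transcript levels differ after it is knocked down. RS4;11 and REH are human cell lines from B-cell acute lymphoblastic leukemia, and RS4;11 carries a fusion of MLL with AF4. iCLIP crosslinks a protein to RNA in living cells, pulls the protein down and sequences the attached RNA. There were 12 samples in 4 groups of 3: IGF2BP3 iCLIP from RS4;11, IGF2BP3 iCLIP from REH, and RNA-seq of RS4;11 cells with a control shRNA or an IGF2BP3 shRNA. The shRNA cells were selected with puromycin at 5 ug per mL for 7 days. Nothing in the labels says whether the samples of a group came from separate cultures, so p-values across iCLIP libraries measure the spread between these samples, which may be technical.

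The depth of the libraries is unknown here, because the files used hold peaks and a table of comparisons. The RS4;11 iCLIP libraries held 3978, 4392 and 5509 peaks, and the REH libraries held 1730, 4620 and 3277. The RNA-seq values came as 1 mean per group, with no value per library, so none of them has an error here.

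The knockdown comparison asked which transcripts differed in level when IGF2BP3 was reduced. IGF2BP3 itself, the target of the shRNA, had a mean normalized count of 40.4 in control and 20.4 in knockdown cells in the authors' deposited table, a log2 fold change of -0.98 with an adjusted p of 0.0777, and so it missed the threshold of 0.05. The paralog IGF2BP1 fell in the authors' deposited table, from 270.0 to 81.4, with a log2 fold change of -1.73 and an adjusted p of 6.0e-05. In all 1831 entries of the authors' deposited table passed an adjusted p of 0.05, of which 1174 were lower and 657 were higher in knockdown cells. The authors' deposited table listed only entries with an adjusted p under 0.1, 2476 in all, so levels of other genes were not analysed here. At an adjusted p below 0.01 the authors' deposited table gave 977 entries, 731 lower and 246 higher.

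**Figure D1:**
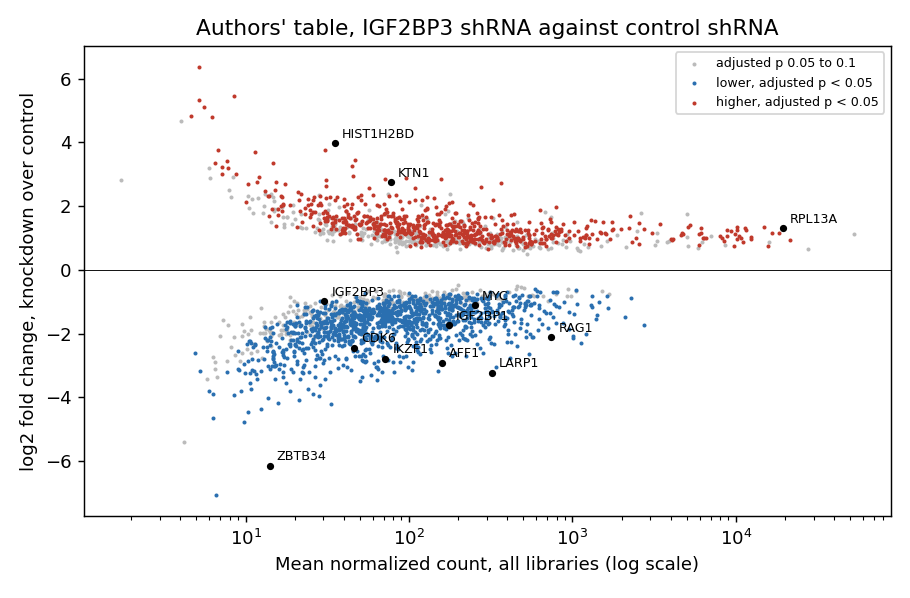
Each point is an entry of the authors' deposited table, with the mean normalized count of all libraries on a log axis and the log2 fold change of knockdown over control on the vertical axis. Blue and red points passed an adjusted p of 0.05 (1174 lower, 657 higher), gray points did not, named genes are in black, and 15 entries with an infinite fold change are not drawn.

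Among entries with a mean normalized count of 10 or more the largest fall was that of ZBTB34, a zinc finger protein, with a log2 fold change of -6.14 in the authors' deposited table, from 27.7 to 0.393 normalized counts. Log2 fold changes in the authors' deposited table were -4.47 for C1orf96, -4.36 for HEG1, -4.22 for SOCS7, -4.16 for KIRREL and -4.08 for DCP1A, a component of mRNA decapping. They were -4.03 for C17orf51, -3.96 for ETV3, -3.90 for the DNA dioxygenase TET3, -3.80 for ZBTB39, -3.73 for SLC23A2 and -3.72 for ATXN1L, again from the authors' deposited table. Knockdown means among these falls were low, such as 1.16 for HEG1, 2.35 for DCP1A, 3.22 for TET3 and 3.38 for ATXN1L in the authors' deposited table. The size of such falls is uncertain. Among the largest rises in the authors' deposited table were the histone genes HIST1H2BD (3.97), HIST1H2AC (3.76) and HIST2H2AA3 (3.46), and CETP (3.70), ANKRD12 (3.34) and CSTA (3.25), as log2 fold changes. The other large rises in the authors' deposited table were CCDC112 (2.96), TMEM59L (2.93), HMGN5 (2.89), LARP7 (2.85), SREK1IP1 (2.84) and RB1CC1 (2.82), and 8 of these 12 genes, the 3 histone genes among them, had means under 10 in control cells.

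Transcripts that earlier work linked to IGF2BP proteins fell where they were called. Of the 27 list members, 6 were in the authors' deposited table, and 5 of these fell while 0 rose. CDK6, a cyclin-dependent kinase, fell from 78.1 to 14.4 normalized counts in the authors' deposited table, with a log2 fold change of -2.44 and an adjusted p of 0.000193. MYC, a transcription factor that drives cell growth, fell from 344.4 to 160.8 in the authors' deposited table (log2 fold change -1.10, adjusted p 0.00825). EIF4EBP2, BCL2 and CTNNB1 had log2 fold changes of -1.38, -2.20 and -1.09 in the authors' deposited table, each past the threshold. PABPC1, the poly(A)-binding protein, had a log2 fold change of 0.86 and an adjusted p of 0.0674 in the authors' deposited table. As a set against the other genes of the table, this list was not shifted (cameraPR, two-sided, adjusted p = 0.325). IGF2BP1 also fell in knockdown cells, with a log2 fold change of -1.73. The falls on this list therefore cannot be told apart from an effect of lower IGF2BP1.

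Ribosomal protein genes rose together. Of 39 in the authors' deposited table, 34 rose, 1 fell (RPL7L1) and 4 did not pass. RPL13A went from 11113 to 27498 normalized counts in the authors' deposited table, a log2 fold change of 1.31, and RPS19 had 1.36. The shift of the list against other genes of the table was upward (cameraPR, two-sided, adjusted p = 1.0e-09). Families chosen after the data were seen moved beside this list in the authors' deposited table, with 19 respiratory chain genes higher and 0 lower, 7 mitochondrial ribosome genes higher and 0 lower, and, on a list of long mRNAs, 47 genes lower and 9 higher (cameraPR adjusted p = 0.000514). Ribosomal protein and histone genes have near-identical copies and pseudogenes, so how reads were split between copies is uncertain for single members. The median log2 fold change of the ribosomal list, 1.06, lay at percentile 98.4 of 10000 random lists matched on mean level. The respiratory chain and mitochondrial ribosome medians lay at percentiles 83.0 and 91.5, within the range of such lists, and the long-mRNA median at 0.

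Histone genes were the other list with a shift. All 8 members past the threshold rose, 9 were in the authors' deposited table, and the linker histone HIST1H1C had a log2 fold change of 2.57 there. The list was shifted upward (cameraPR, two-sided, adjusted p = 0.00169), with a median log2 fold change of 2.82. Because polyadenylated RNA was selected, these values cover histone transcripts in that fraction only. Total histone mRNA was not measured, so a rise of it is not shown. No value per library was used here, so neither list test could be run with an estimated correlation between genes.

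Genes of the B-cell lineage went both ways, with 12 lower and 4 higher past the threshold among 21 in the authors' deposited table. RAG1, a recombinase of immunoglobulin genes, had a log2 fold change of -2.11 in the authors' deposited table, the transcription factor IKZF1 had -2.78, FOXO1 had -2.25 and the cytokine receptor IL7R had -1.47. Of targets of the MLL-AF4 fusion, 10 were lower and 1 was higher in the authors' deposited table, among them RUNX1 (-1.59), MEF2C (-1.34) and MBNL1 (-2.03). Of cell cycle genes, 8 were lower and 0 were higher in the authors' deposited table, with log2 fold changes of -1.91 for E2F2, -1.30 for FOXM1 and -1.14 for MCM4. Interferon response genes had 3 lower and 6 higher in the authors' deposited table, with IFI16 at 1.76, IFIH1 at 2.20 and OAS3 at -1.92. None of these 4 lists passed as a set (cameraPR adjusted p = 0.336 for the B lineage, 0.0973 for MLL-AF4 targets, 0.0934 for the cell cycle and 0.0934 for the interferon response).

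Of microRNA machinery genes 4 were lower and 0 higher in the authors' deposited table, with TNRC6C at -3.22, EIF2C1 at -1.93 and DGCR8 at -1.69, at a set-level adjusted p of 0.0973. Of cholesterol genes 4 were lower and 0 higher in the authors' deposited table, among them HMGCS1 (-1.55) and SREBF2 (-1.45), at a set-level adjusted p of 0.288. Translation factors had 2 lower and 5 higher in the authors' deposited table, with EIF4G1 at -1.86 and EIF2S2 at 1.88, at a set-level adjusted p of 0.0910. Other RNA-binding proteins of mRNPs had 5 lower and 1 higher in the authors' deposited table, with DDX6 at -2.07 and G3BP2 at -1.39, at a set-level adjusted p of 0.198. MYC targets had 3 lower and 0 higher at a set-level adjusted p of 0.833, with a negative median and an upward test. Glycolysis and hypoxia genes had 2 lower and 1 higher (adjusted p = 0.223), with HK2 at -1.69 in the authors' deposited table, and adhesion genes had 2 lower and 5 higher (adjusted p = 0.319), with MSN at -1.69 and S100A4 at 1.42. Lists with under 5 members in the table were counted only. They were p53 and apoptosis (2 lower, 2 higher), ATF4 stress (1 and 1), heat shock (0 and 2), NF-kB signaling (2 and 1) and m6A machinery (2 and 1). As checks for other blood cells, myeloid markers had 1 lower (MPO, -2.22 in the authors' deposited table) and 1 higher (CST3, past the threshold), erythroid markers had 1 lower (TFRC), and T and NK cell markers had 0 of 19 in the table. Adjusted over the list alone, 6 of 6 IGF2BP-linked genes in the table, 8 of 9 cell cycle genes, 11 of 11 MLL-AF4 targets, 11 of 12 interferon genes, 3 of 8 MYC targets, 3 of 8 glycolysis and hypoxia genes, 8 of 8 adhesion genes, 5 of 6 cholesterol genes, 10 of 10 mRNP genes and 5 of 5 microRNA machinery genes passed. For B-lineage, histone, translation factor and ribosomal protein genes this count was fixed by the selection of the table on p, since no member in it could fail, and it carries no information. In the mRNP and MLL-AF4 lists a member could fail only with a raw p near the highest in the table, 0.0186. Their full counts carry little information, and the selection also raised the counts of the other lists.

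**Figure D2:**
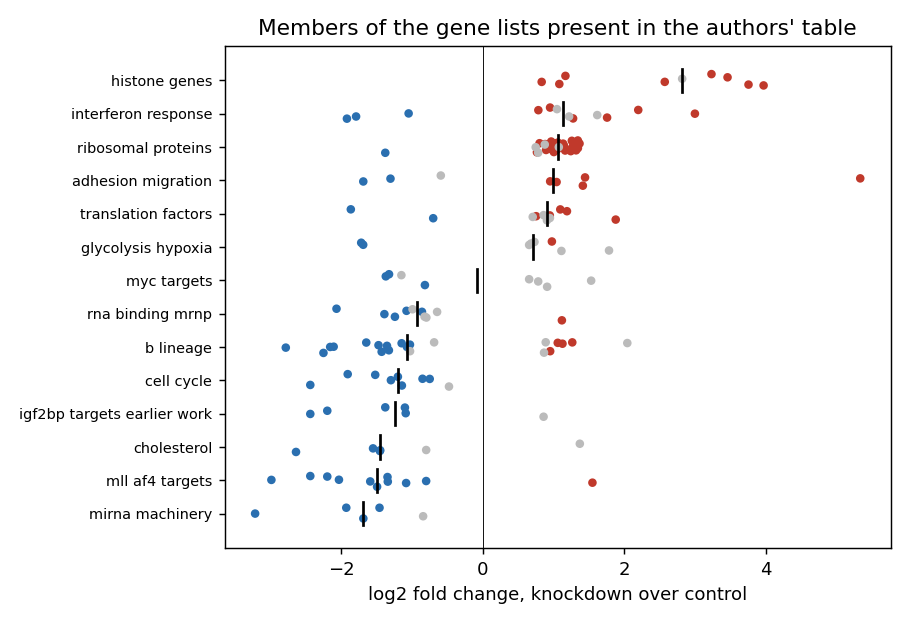
Each point is a list member in the authors' deposited table, placed by its log2 fold change of knockdown over control, in blue or red where the adjusted p was below 0.05 and in gray otherwise. Black bars are medians, and histone genes had the highest, 2.82.

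The iCLIP comparison asked where IGF2BP3 bound in each line and how alike the lines were. RS4;11 libraries had 4626 ± 792 peaks and REH libraries 3209 ± 1446 (SD, n = 3 each), a ratio of geometric means of 1.54 that did not exceed the spread between libraries (exact permutation test, two-sided, p = 0.3, smallest possible p 0.1). Genes with a peak numbered 3174 ± 495 in RS4;11 and 2420 ± 986 in REH (exact permutation p = 0.4). Without REH replicate 1 the log2 difference in peaks fell from 0.63 to 0.24, and without REH replicate 2 it was 0.94. Peaks had a median width of 46.0 ± 1.73 bases in RS4;11 and 40.7 ± 0.577 in REH (SD, n = 3).

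The noncoding RNA MALAT1 carried the most peaks among the genes named here, 71.3 ± 7.77 per RS4;11 library (SD, n = 3), with 47, 79 and 55 in the REH libraries. In RS4;11 it was followed by NCL (17.0 ± 3.46), which encodes nucleolin, the chaperone gene HSP90AA1 (14.7 ± 4.04), HMGB1 (13.3 ± 1.53), HNRNPU (13 ± 1), the elongation factor gene EEF1A1 (12.7 ± 2.08), PTMA (11.3 ± 1.15), HSP90AB1 (10 ± 2), GAS5 (9.67 ± 2.08) and NEAT1 (9.67 ± 2.08), each with n = 3. In REH the leading genes after MALAT1 included GAS5 with 8, 13 and 11 peaks, EEF1A1 with 3, 13 and 4, SNHG1 with 9, 9 and 8, and DDX17 with 4, 11 and 8. GAS5 and SNHG1 are host genes of small nucleolar RNAs. The samples hold no control iCLIP library, so peak numbers per gene cannot be told apart from transcript abundance.

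CDK6 had 8, 10 and 6 peaks in the RS4;11 libraries and 1, 1 and 0 in the REH libraries. On the minus strand of chromosome 7 (hg19) its RS4;11 peaks lay between 92235889 and 92244225, in 13 separate regions, of which 4 had a peak in all 3 RS4;11 libraries and 1 of those 4 also had a REH peak. The tallest, at 92243966 to 92244042, held 79 reads. MYC had 2 peaks in each RS4;11 library and 0, 2 and 0 in the REH libraries. Its RS4;11 peaks lay between 128751866 and 128753652 on the plus strand of chromosome 8 (hg19). Whether these positions are exon, intron or UTR was not analysed here. The series holds no RNA-seq of REH, so fewer REH peaks on these genes cannot be told apart from lower transcript levels in REH. Of the 27 genes linked to IGF2BP proteins earlier, 16 had a peak in 2 or more RS4;11 libraries and 6 in 2 or more REH libraries.

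**Figure D3:**
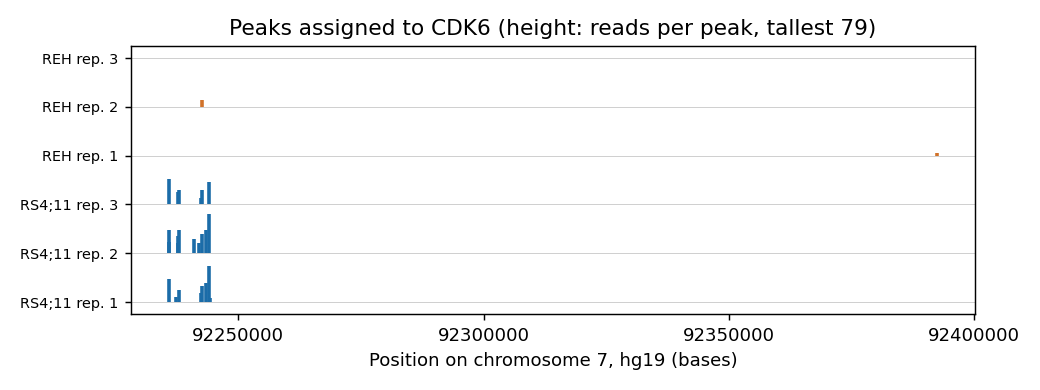
Vertical lines mark the centers of peaks assigned to CDK6 along chromosome 7 (hg19), 1 row per iCLIP library, with height in proportion to the reads of the peak. RS4;11 libraries held 8, 10 and 6 peaks, and REH libraries 1, 1 and 0, with the peak of REH replicate 1 outside the stretch of the RS4;11 peaks.

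RS4;11 libraries shared 53.4% of peaks with each other and 37.4% with a REH library, while REH libraries shared 56.8% with each other and 57.1% with an RS4;11 library. These percents depend on how many peaks the other library held, and the difference between the lines was not tested. The Jaccard index of the gene sets, which treats both libraries of a pair alike, averaged 47.8% within RS4;11, 41.3% within REH and 37.9% across lines. Over both lines 55.1% of a library's peaks overlapped a peak of another library of its line and 47.2% a peak of a library of the other line, a difference of 7.83 percentage points (1 base or more, same strand, ordered pairs). No other split of the 6 libraries gave a larger difference (permutation over 10 splits, share 0.1, the smallest possible).

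**Figure D4:**
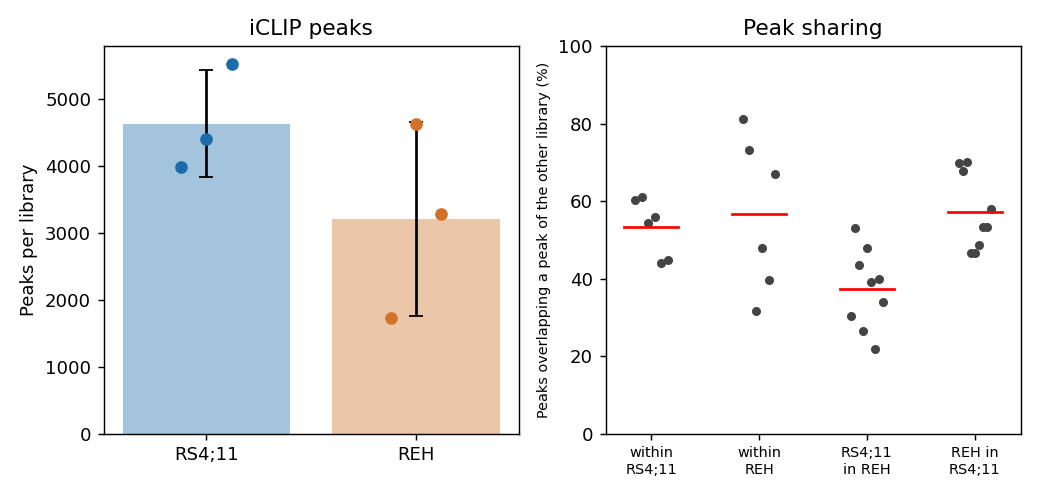
The left panel shows peaks per library as points, with bars for the mean and error bars for the SD over 3 libraries (4626 ± 792 and 3209 ± 1446). The right panel shows, for each ordered pair of libraries, the percent of peaks of the first that overlap a peak of the second, with red lines at the means of 53.4%, 56.8%, 37.4% and 57.1%.

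Genes bound in 2 or more libraries numbered 2818 in RS4;11 and 2206 in REH, and 1615 were bound in both. Among the 2466 genes of the knockdown table, 248 were bound in both lines, 283 in RS4;11 alone, 63 in REH alone and 1872 in neither, an odds ratio of 26.0 with a 95% interval of 19.1 to 35.8 (Fisher's exact test, two-sided, p = 1.0e-127, genes not being independent replicates). With all genes that had a peak in any library as the background, a choice made after seeing the data, the odds ratio was 6.002. Without REH replicate 2 or 3 the odds ratio was 43.5 or 43.8. Genes were not matched on transcript level in this comparison. The overlap therefore cannot be told apart from peaks being found more easily on abundant transcripts in both lines.

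In RS4;11, 221 genes had a peak in all 3 libraries and in 0 REH libraries, led by the proliferation antigen gene MKI67 (6 ± 1.73 peaks, SD, n = 3), PRRC2C (6 ± 3), PRKDC (5 ± 2.65), MYO18A (4.67 ± 0.577), PABPC3 (4.67 ± 1.15), ANP32A (4 ± 1), ANKRD11 (3.67 ± 2.08) and BRD2 (3.67 ± 1.53). In REH, 79 genes had a peak in all 3 libraries and in 0 RS4;11 libraries, among them PCLO, SLC25A30, SSR3, USP39, ZFAND4, ANKAR, DLEU2 and ELF1, with 1 to 3 peaks per library. Of these 79 genes 16 were small structured RNAs and 23 had no symbol, beside 4 and 14 of the 221 in RS4;11. PABPC3 is a near copy of PABPC1, so its peaks are uncertain. Transcript levels in REH were not measured in this series. A peak found in 1 line alone therefore cannot be told apart from a difference in transcript level between the lines. Leaving out a library also loosens the rule, since fewer libraries then need a peak or must lack one, and the counts rose: without REH replicate 2 the RS4;11 count was 420, without RS4;11 replicate 1 or 2 it was 387 or 342, and without REH replicate 1 the REH count was 239.

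The last comparison set binding beside the knockdown, both from RS4;11. Since IGF2BP1 also fell in knockdown cells, changes of bound genes cannot be assigned to IGF2BP3 alone. Genes bound in RS4;11 were more frequent among the genes that fell. Of 1173 genes that fell, 28.3% were bound in 2 or more RS4;11 libraries, against 15.4% of the other genes of the table, an odds ratio of 2.17 with a 95% interval of 1.77 to 2.66 (Fisher's exact test, two-sided, adjusted p = 1.3e-14). Of 655 genes that rose, 14.4% were bound, against 24.1% of the others, an odds ratio of 0.527 with a 95% interval of 0.408 to 0.675 (adjusted p = 9.1e-08), but the others were mostly genes that fell. Against the 638 genes of the table past the threshold in neither direction, of which 16.5% were bound, a comparison added after seeing the data, the odds ratio was 2.00 (95% interval 1.56 to 2.59, Fisher p = 1.1e-08) for genes that fell and 0.851 (0.621 to 1.16, Fisher p = 0.317) for genes that rose, so a lower share among risen genes was not found there. Of the bound genes with the smallest p, LARP1, an mRNA-binding protein, had a log2 fold change of -3.22 in the authors' deposited table, AFF1 had -2.92, SMC1A had -2.62, WASF2 had -2.28, NOLC1 had -2.45, DIAPH1 had -2.00 and CRKL had -2.48. Bound genes that rose in the authors' deposited table included KTN1 (2.75), PCM1 (2.56), TAF1D (2.26), NUCB2 (2.04), PPIG (2.30), SYF2 (1.98) and TOP2B (1.55), and 23 of the 94 bound genes that rose encoded ribosomal proteins.

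The median log2 fold change was -1.24 for 528 bound genes and -0.75 for 1542 genes with no RS4;11 peak, a difference of -0.49 (permutation within 10 bins of mean level, 100000 resamples, two-sided, p = 0.0125). In a table selected on p, such medians also depend on the share of genes that fell. Of called genes, 56.4% fell with 0 RS4;11 libraries, 81.3% with 2 and 75.7% with 3. The difference in medians therefore does not show by itself that bound genes fell further. Without RS4;11 replicate 1, 2 or 3 the difference was -0.47, -0.46 or -0.36 and the permutation p was 0.0901, 0.152 or 0.116. With genes bound in all 3 libraries the difference was -0.50 (permutation p = 0.421), and with the better-scoring 50% of peaks -0.36 (permutation p = 0.207). With a peak in 1 or more libraries it was -0.50 (permutation p = 1.0e-05, the smallest that the resamples allow), and without the lists of long and short mRNAs, left out after seeing the data, -0.48 (permutation p = 0.00026). Genes bound in REH gave a difference of -0.40 (permutation p = 0.00579) and an odds ratio among fallen genes of 1.96, but 248 of the 311 REH-bound genes of the table were also bound in RS4;11. Among called genes with no RS4;11 peak the odds ratio of falling for REH-bound genes was 1.65, with a 95% interval of 0.696 to 4.21. The difference between the lines was not tested.

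**Figure D5:**
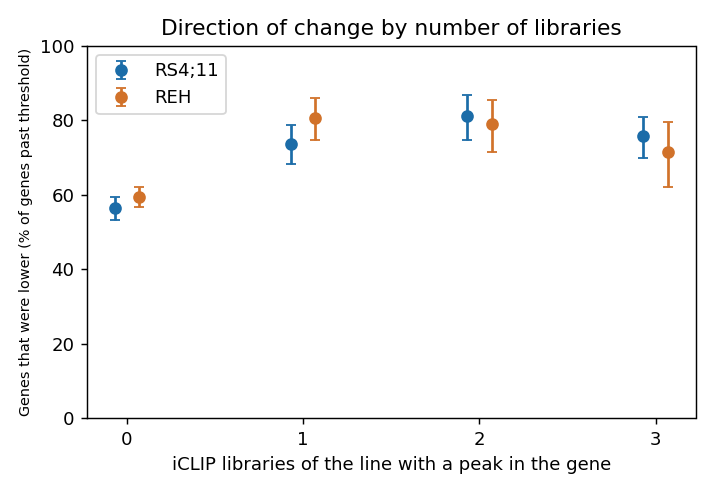
For genes past the knockdown threshold, the percent that were lower is plotted against the number of iCLIP libraries of a line with a peak in the gene, with exact 95% binomial intervals. With 0, 1, 2 and 3 RS4;11 libraries the percent was 56.4, 73.7, 81.3 and 75.7.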

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

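Peaks over a stretch of chromosome 1 (hg19, 564876 to 570227) that holds pseudogene copies of mitochondrial genes, among them MTND2P28, MTCO1P12 and MTCO3P12, are given here because the comparisons of the report rest on peaks and genes and use reads per peak only for ties in the ranking of peaks, and because these reads lay far above the limit of 3 that a count of 0 allows. The read shares of RNA classes elsewhere in this closing section do use reads per peak. The lowest library held 1501 reads there, RS4;11 libraries held 1501, 1526 and 1752, and REH libraries 3153, 7682 and 4674. These were 2.19%, 2.01% and 2.07% of the peak reads in RS4;11 and 10.001%, 7.91% and 7.41% in REH, with each interval counted once even where it was listed under more than 1 gene, in the stretch and in the total, unlike the shares of RNA classes, which use all listed peaks. The peak files held 0 peaks on the mitochondrial chromosome. No explanation was tested.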

How the results depend on the processing

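All alternatives were fixed beforehand except the recomputed adjustment, the leaving out of gene lists, the any-peak background, REH-bound genes, the p from the distance to 0, the genes past the threshold in neither direction and the stratified odds ratio, which were chosen after seeing the data. Of 180 alternative values for 27 results, 159 kept their direction and side of the threshold, 14 counts moved by over 1.5 times, 6 lost the threshold and 1 reversed. The reversed value was the shift of MYC targets, upward in the main test and downward with ranks (adjusted p = 0.650), past the threshold in neither; the cause was not tested. Entries past the knockdown threshold numbered 977 (731 lower, 246 higher) at an adjusted p below 0.01, and 1016 were higher at 0.1; these follow from the thresholds themselves. Genes bound in one line alone numbered 895 (609 in RS4;11, 286 in REH) with 2 or more libraries against 0, a looser rule, and leaving out single libraries gave 396 to 514 in all, 231 to 420 in RS4;11 and 94 to 239 in REH, where fewer libraries are needed. The difference in median log2 fold change of bound genes lost its call in the permutation test with 3 of 3 libraries (-0.50, p = 0.421), with the better-scoring 50% of peaks (-0.36, p = 0.207) and without single RS4;11 libraries (-0.47 to -0.36, p = 0.0901 to 0.152); the cause was not tested. The lower share of bound genes among risen genes lost its call against genes past the threshold in neither direction (odds ratio 0.851, Fisher p = 0.317), since the other genes of the main test were mostly fallen ones. The genes in neither direction were more often higher than lower, so this was no comparison with unchanged genes. The ribosomal protein and histone lists passed under every list setting tried. The planned adjustment over the table alone was not run, since every entry is already under 0.1, nor were results on peak location and motifs. With the replicate block, pairing lines by number, the log2 difference in peaks was 0.63 (exact p = 0.5) and the sharing difference 7.32 points (exact p = 0.25, the smallest 3 pairs allow); deviations of same-numbered libraries correlated at -0.048, 0.043 and 0.027, so they share only a number. No paired analysis was possible for the knockdown because no value per library was used.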

Other observations

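The gene families, the classes of RNA and the tests of length, rescaling and peak number in this part were chosen after the data were seen. Genes of the respiratory chain rose in the authors' deposited table, 19 higher and 0 lower of 27 (cameraPR adjusted p over the added families 6.1e-07), as did genes of the mitochondrial ribosome (7 higher, 0 lower, adjusted p = 0.000771) and HLA genes (6 higher, 0 lower, adjusted p = 0.00125). Chromatin regulators were mostly lower in the authors' deposited table, 37 lower and 5 higher (adjusted p = 0.000143). Among them were MLL2 at -2.60, BAZ2A at -2.30 and ARID1A at -2.18 as log2 fold changes. Against random lists matched on mean level, the respiratory chain median lay at percentile 83.0 and the mitochondrial ribosome median at 91.5. Those medians were within the range of such lists. In a table selected on p such medians also depend on the share of genes that rose. The percentiles therefore do not show whether level-matched genes rose as often or as much. The HLA median lay at percentile 95.05 and the chromatin regulator median at 0.

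Of 56 called genes on a list of long mRNAs 47 fell and 9 rose, beside 1174 lower among all 1831 called entries, while the ribosomal protein, respiratory chain and mitochondrial ribosome families, whose mRNAs are short, had 34, 19 and 7 genes higher. Of the called long-mRNA genes 16.1% rose (exact 95% interval 7.62% to 28.3%), among them KTN1, PCM1 and TOP2B, beside 36.5% of other called genes. The list was chosen after directions were seen and gene lengths were not used here, so length as the only driver or as a part of the pattern stays open. A rescaling by a few abundant genes would move all other genes by 1 log amount, so by arithmetic it opens no gap between families and could only shift them together. The median log2 fold change of the long-mRNA list minus that of the respiratory chain, mitochondrial ribosome and proteasome families was -2.51, which restates the pattern in families chosen after their directions were seen and was not a test, and such a shift stays open. An effect of the knockdown was not tested against these.

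Genes bound in RS4;11 fell more often than others. With genes matched on mean level over all RNA-seq libraries, the difference in medians gave a permutation p of 0.0125. An odds ratio stratified by that mean, chosen after seeing the data, was 2.62 (95% interval 2.12 to 3.23). It was 2.17 unstratified, and 2.42 to 2.56 stratified without single RS4;11 libraries. That mean includes the knockdown libraries, so at an equal mean a fallen gene had a higher control level than a risen gene. The matching therefore cannot decide whether a difference in control level was the whole cause, and this stays open. The matched difference in medians, -0.49 with all libraries, lost its call without RS4;11 replicate 1, 2 or 3 (-0.47, -0.46 and -0.36, permutation p = 0.0901, 0.152 and 0.116), with the better-scoring 50% of peaks (-0.36, permutation p = 0.207) and with 3 of 3 libraries (-0.50, permutation p = 0.421). Without the long- and short-mRNA lists the odds ratio of falling among called genes was 3.15 (95% interval 2.34 to 4.29), but those lists covered only 121 of 1828 called genes, so longer transcripts collecting more peaks cannot be told apart from binding, against the rule written beforehand. Among called genes with no RS4;11 peak, those bound in 2 or more REH libraries had an odds ratio of 1.65 (0.696 to 4.21, 27 genes), which leaves open a property shared by genes bound in any line; with a peak in 1 or more REH libraries, a definition other than the one fixed, it was 2.75 (1.57 to 5.02).

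Small structured RNAs took 12.2 ± 0.908% of peak reads in REH and 5.33 ± 0.737% in RS4;11 (SD, n = 3; exact permutation p = 0.1, the smallest possible). REH replicate 2, with more peaks than RS4;11 replicates 1 and 2, had 11.2%, above the highest RS4;11 limit of 6.36%, but it is 1 library and depth is unknown, so lower depth in REH stays open. These shares rest on the number in the peak names, read as reads. Without the 5 leading genes of the class in each library the lowest REH share was 8.64% and the highest RS4;11 share 5.04%, which argues against single abundant genes. A difference between the lines or between their library preparations remains a candidate explanation that was not tested. MALAT1 and NEAT1 together took 10.4 ± 0.851% of peak reads in RS4;11 and 6.31 ± 0.777% in REH.

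The number of genes with a peak in all libraries of one line and none of the other was 300, and 1 of the 10 splits of the 6 libraries, the real one, gave as many. The highest of the other splits gave 96. Too few splits exist for a share under 0.05.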
